A study of Homo sapiens with 24 samples.

How the data were processed

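Messenger RNA levels were measured by RNA sequencing in 24 libraries of TYUC-1, a human neuroendocrine esophageal carcinoma cell line grown in suspension. Of 2 engineered lines, one expressed TAp63 and the other ΔNp63 under doxycycline at 1 µg/ml. TAp63 and ΔNp63 are the products of alternative promoters of TP63, a transcription factor of squamous epithelia: TAp63 carries an N-terminal transactivation domain that ΔNp63 lacks. Cells received doxycycline for 0, 1, 3 or 6 days within a 6 day course and the vehicle DMSO for the rest of it, with 3 libraries per line and day, which gives 8 groups. The series describes its replicates as biological and does not say how the cultures were kept apart, so p-values measure the spread between these libraries. Each sample also has a treatment label naming EPZ-6438, an inhibitor of the histone methyltransferase EZH2, for as many days as the doxycycline, whereas titles, induction labels and the series design name only p63 induction. The labels do not settle whether the inhibitor was present, so each comparison is one of days of induction that would also differ in the inhibitor if it was used.

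Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra kit and sequenced on a NextSeq 500/550. Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 to hg38 and counted with featureCounts 1.6.1; the notes also name DESeq2, without a version. Per the file header, the deposited counts were made with featureCounts 2.0.0 on the UCSC refGene annotation of hg38, a version that differs from the notes. The header's command counted paired fragments over whole transcript spans, introns included, without a strand option and without options for multi-mapping or multiply overlapping fragments. A gene's count therefore includes unspliced RNA, TP63 isoforms are summed, and fragments that overlap 2 genes were left uncounted by either. Values are uncertain for genes with an overlapping or antisense neighbour: ART3 with CXCL10 and CXCL11, CDKN1A with DINOL, POU2F3 with LOC649133, SYP with SYP-AS1, ITGA6 with ITGA6-AS1, MTHFD2 with SLC4A5, LIMS2 with GPR17 and ALK with LOC105374389. Near-identical copies, such as the SPRR2 genes and the fetal globins HBG1 and HBG2, are uncertain too. A microRNA gene lies within TP63, PADI3, FXYD3, B2M, COL3A1, PRSS8, NFATC2 and TNFRSF1B.

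The deposited table held raw counts, not normalized, for 28278 genes, of which 6005 had 0 counts in all libraries. Totals ran from 1530847 counts, in replicate 3 of ΔNp63 day 1, to 22019974 per library, with a second lowest of 6375963. No pair of replicates agreed within sampling noise: the lowest chi-square per degree of freedom within a group was 5.05, so each library was counted separately. Intervals given for genes with few counts are 95% and cover counting error only. For a bound, a group with 0 counts was set to 3 counts over the group, and the other group's count was taken as observed. A bound is therefore not a 95% limit of the ratio.

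Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, TMM normalization, glmQLFit and glmQLFTest). The 24 libraries entered one model with a mean per group and 16 residual degrees of freedom, and 15642 genes were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each line was compared with its own day 0 at days 1, 3 and 6, and day 6 was compared with day 1. The difference between the lines' responses was tested as an interaction, TAp63 minus ΔNp63, and the lines were compared at day 0. Levels are CPM on TMM-adjusted library sizes, as mean ± SD over n = 3 libraries. Log2 changes are given ± SE, taken as the absolute log2 change divided by the square root of the quasi-likelihood F. This SE is approximate, above all for genes near 0 counts in a group. The median log2 change over all genes was at most 0.0154 from 0 in any comparison.

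Of 25 gene lists chosen before the data were examined, as were the comparisons and their main tests, 24 had at least 5 tested members. The list of mitochondrially encoded protein genes was not analysed here. The lists cover basal squamous epithelial, squamous differentiation, neuroendocrine, p53-family target, hemidesmosome and basement membrane, desmosome, simple epithelial, mesenchymal transition, Notch pathway, G1/S, G2/M, polycomb repressive complex, HOX cluster, MHC class I, interferon response, ATF4 stress response, immediate early and heat shock, cholesterol synthesis, and hypoxia and glycolysis genes. Tuft cell, columnar, fibroblast, immune cell and endothelial markers stand for other cell types or states. Of the 33 basal squamous genes, 21 of them tested, 11 are also in other lists, as are 3 of the 47 squamous differentiation genes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists and the 6 comparisons with day 0; the list tests of the day 6 difference were adjusted among themselves. Camera compares a list with all other genes, and fry tests whether a list's genes move on balance one way.

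Genes were named by a rule. TP63, KRT5, KRT14, NEUROD1, INSM1, CHGA, SYP, EZH2, CDKN1A, SOX2 and POU2F3 were always named where tested; KRT14, INSM1, CHGA and SOX2 were too low to be tested. At day 6 the 8 largest rises and 8 largest falls were named among called genes with at least 5 CPM in the higher group and no overlap between the libraries of the groups, at days 1 and 3 the 4 largest each way, and in the other comparisons the 6 largest each way, for the interaction without the condition on overlap. Up to 2 risen and 2 fallen members of each list were named at day 6. Other genes named in the text, among them further called list members, the genes of the day 3 difference and ANKS4B, RCAN1, ST6GALNAC2 and CACNA1H, were chosen after their values were seen. Some genes that the rule names are not reported here.

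The alternatives tried were DESeq2 size factors, no count filter, DESeq2 1.42.0 with a Wald test, replicate number as a block, only the libraries of the groups compared, TP63 left out of the library sizes, and each library left out in turn; for lists an estimated correlation, fry and the block; and for the comparison of the lines across genes a minimum of 5 CPM and the block. A fit without ΔNp63 day 1 replicate 3, and that fit with the block, were added after seeing the data, because this library stood apart. Replicate numbers come from the titles. Deviations of same-numbered libraries from their group means were correlated above 0.1 in all 3 pairs for 7 of 9 comparisons of a pair of groups, with a lowest value of 0.228, so the numbers were taken to pair the libraries there; the block lowered the common biological coefficient of variation from 0.216 to 0.152. On simulated counts for TAp63 day 6 against day 0, edgeR recovered 85 of 100 genes changed by 2-fold and 100 of 100 changed by 4-fold, with 8 false calls among 15492 genes. The changed genes were drawn from those above the median level, so recovery of lower genes was not tested. The simulated counts held neither shared deviations of same-numbered libraries nor a library that stood apart.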

Results

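RNA was sequenced from TYUC-1 cells, a line derived from a neuroendocrine carcinoma of the esophagus, before and after induction of either TAp63 or ΔNp63. The series concerns the part that p63 plays in the choice between squamous and neuroendocrine identity in the esophagus. Each line was sampled at days 0, 1, 3 and 6 of doxycycline with 3 libraries per day, doxycycline-treated cells without a p63 construct were not analysed here, and means are over n = 3 libraries with their SD. Totals ran from 1530847 to 22019974 counts. A single library stood apart: replicate 3 of ΔNp63 day 1 had the lowest total and scored -193.9 on a first principal component that held 49.6% of the variance, where the other 23 libraries lay between -17 and 24.95. It held 1730 CPM of the fetal globin HBG2 and 69.2 CPM of TP63. It enters the estimate of spread of every comparison, so each count of changed genes is followed by the count without it. Values of SYP, POU2F3, CDKN1A, ITGA6, MTHFD2, ART3, LIMS2 and ALK are uncertain, since each overlaps another gene and strand was not counted.

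TP63, the induced gene (hg38, chromosome 3, 189596746 to 189897279), rose in both lines at each time. In the TAp63 line it went from 2.93 ± 0.0361 CPM at day 0 to 371 ± 45.1 at day 1, 558 ± 92.8 at day 3 and 655 ± 41.3 at day 6. The log2 changes were 6.98, 7.57 and 7.80 (edgeR adjusted p = 6.51e-07, 1.32e-07 and 7.12e-08). In the ΔNp63 line it went from 4.35 ± 0.517 CPM to 455 ± 342, 865 ± 140 and 926 ± 100. The log2 changes there were 6.73, 7.64 and 7.74 (edgeR adjusted p = 7.32e-07, 1.35e-07 and 5.24e-08). The induction at day 6 differed between the lines by 0.06 ± 0.652 on the log2 scale (edgeR adjusted p = 1), and the counts do not tell the isoforms apart. At ΔNp63 day 1 the other replicates held 721 and 576 CPM, and without replicate 3 the log2 change was 7.23. With only the libraries of the groups compared, the day 1 change of 6.72 had an edgeR adjusted p of 0.942.

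**Figure D1:**
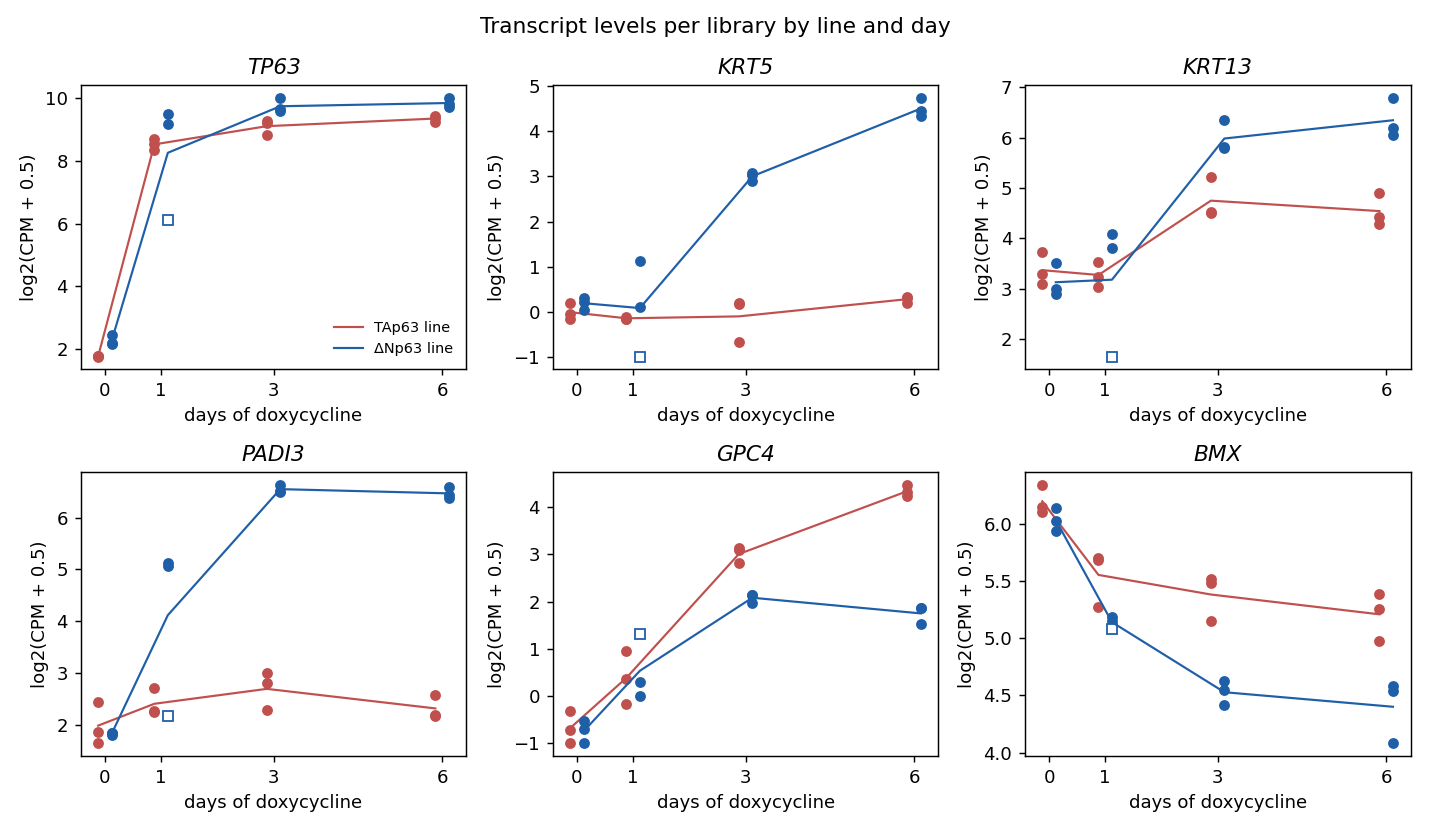
Levels of TP63, KRT5, KRT13, PADI3, GPC4 and BMX as log2(CPM + 0.5) against days of doxycycline, 1 point per library, red for the TAp63 line and blue for the ΔNp63 line, with lines through the means of the log values and an open square for ΔNp63 day 1 replicate 3. TP63 rises in both lines, whereas KRT5 reaches 22.5 CPM at day 6 in the ΔNp63 line and 0.711 CPM in the TAp63 line.

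By day 6 of ΔNp63 induction genes of stratified squamous epithelium had risen. KRT5, the type II keratin of basal cells (chromosome 12, 52514575 to 52520394), rose from 0.641 ± 0.108 to 22.5 ± 3.46 CPM (log2 change 5.11 ± 0.390, edgeR adjusted p = 5.84e-08). PADI3, a peptidylarginine deiminase of epidermis and hair follicle (chromosome 1, 17249098 to 17284232), rose from 3.04 ± 0.0653 to 88.5 ± 7.28 CPM. KRT13, a keratin of the suprabasal esophagus (chromosome 17, 41500981 to 41505612), rose from 8.43 ± 2.13 to 82.7 ± 23.8 CPM. TGFBI, an extracellular matrix protein induced by TGF-β (chromosome 5, 136028988 to 136063818), rose from 1.70 ± 0.540 to 43.8 ± 4.54 CPM. FXYD3, a regulator of the sodium pump (chromosome 19, 35115823 to 35124324), went from 1.69 ± 0.561 to 35.9 ± 2.83 CPM. Among the called genes with at least 5 CPM in the higher group and no overlap between libraries, SIPA1L2 (log2 change 5.92), LIPF, a gastric lipase (4.62), and IL23R, the interleukin 23 receptor (4.47) were others with large rises. The largest falls among such genes reported here were those of ART3 (-2.33), PPP1R1B (-2.002), SLC1A7, a glutamate transporter (-1.90), and ATP12A, a proton pump (-1.75). CD6 (-1.67), BMX, a Tec family kinase among the tuft cell markers (-1.63), TARP (-1.54) and the potassium channel gene KCNN4 (-1.51) fell too.

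Of 30 tested squamous differentiation genes 7 rose in the ΔNp63 line at day 6 and edgeR called 0 lower (13 rose and 3 fell adjusted over the list alone). At an unadjusted p under 0.05, 4 were lower, DESeq2 called 10 higher and 1 lower, and with the replicate block and without ΔNp63 day 1 replicate 3 edgeR called 14 higher and 4 lower. The risen members were KRT13 (log2 change 3.31), S100A8 (3.26), KRT4 (3.01), CRNN (1.80), S100A14 (1.54), EMP1 (1.12) and the desquamation protease KLK7. KLK7 had 0 counts at day 0 and was 4.99-fold higher at day 6 at its bound, with day 0 set to 3 counts. Camera placed the list above other genes (adjusted p = 1.43e-07; adjusted p = 0.147 with an estimated correlation), with a median log2 change of 0.353 that was the same with KLK7 at its bound. Among 21 basal squamous genes 5 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 2.4e-08, adjusted p = 0.173 with an estimated correlation). Besides KRT5 the risen genes were TRIM29 (26.99 ± 5.07 to 122 ± 6.83 CPM, log2 change 2.18), KRT15 (2.02), S100A2 (1.77) and FAT2 (1.14). ITGA6, the α6 integrin of hemidesmosomes, fell by 0.81 on the log2 scale.

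Several groups outside the squamous program moved with ΔNp63 at day 6. Among 13 mesenchymal transition genes TGFBI, FN1 (35.3 ± 3.88 to 137 ± 8.87 CPM) and LOX (log2 change 1.42) rose, while VIM stood at -0.75 without passing. Adjusted over the list alone 3 rose, and camera called the list higher (adjusted p = 3.31e-06), as it did with an estimated correlation (adjusted p = 0.0403). VIM varied with replicate number, at 21.6, 3.07 and 0.197 CPM in replicates 1, 2 and 3 of day 0. At day 6 it stood at 12, 0.719 and 0.632 CPM. HBG2 had the same order at day 0, with 30.6, 5.22 and 0.131 CPM. Whether the change of VIM belongs to induction or to what set the replicates apart was not tested. B2M, the light chain of MHC class I, rose from 436 ± 18 to 1075 ± 126 CPM (log2 change 1.30, edgeR adjusted p = 8.06e-07). It was the called member among 18 MHC class I genes (1 adjusted over the list alone; camera adjusted p = 0.000654, adjusted p = 0.0897 with an estimated correlation). IFIT2 (1.92), IFIT1 (1.70) and IFI6 (1.48) rose among 22 interferon response genes (3 adjusted over the list alone; camera adjusted p = 0.00852, and 0.0403 as the adjusted p with an estimated correlation). IFIT2 and IFIT1 were low throughout, at 0.517 ± 0.38 and 0.472 ± 0.129 CPM at day 0. At day 6 they stood at 2.05 ± 0.404 and 1.52 ± 0.355 CPM. Tuft cell markers were lower as a list of 12, with BMX called over all genes and 5 members lower when adjusted over the list alone (camera adjusted p = 6.77e-09; adjusted p = 0.0403 with an estimated correlation). GRHL1 (0.95), PRSS8 (0.85) and KRT19 (0.79) rose among 23 simple epithelial genes (3 adjusted over the list alone; camera adjusted p = 0.0239, adjusted p = 0.677 with an estimated correlation).

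The G2/M, ATF4 and G1/S lists lay lower in the same comparison. AURKA, a mitotic kinase, fell from 119 ± 4.12 to 93.4 ± 2.62 CPM, the called member among 35 G2/M genes (1 adjusted over the list alone; camera adjusted p = 3.31e-06, adjusted p = 0.126 with an estimated correlation). MTHFD2, a mitochondrial folate enzyme, fell by 0.51 on the log2 scale among 33 ATF4 targets (4 fell adjusted over the list alone; camera adjusted p = 9.82e-08, adjusted p = 0.0807 with an estimated correlation). The 32 G1/S genes lay lower at a camera adjusted p of 0.0446, with an adjusted p = 0.614 with an estimated correlation and 0.0562 without ΔNp63 day 1 replicate 3. EdgeR called 0 of them, with 0 at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2, or 1 lower without that library with the replicate block. LAMB1, a laminin chain, rose (0.72) and ITGA6 fell among 23 hemidesmosome genes (3 and 1 adjusted over the list alone). Camera called that list higher at an adjusted p of 0.0479 (adjusted p = 0.299 with an estimated correlation), and 0.0584 with the replicate block.

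The neuroendocrine identity genes that could be tested gave no common shift in the ΔNp63 line at day 6. The list holds 57 genes, of which 25 were tested, with INSM1 and CHGA too low for it. Members already low before induction left little room to show a fall, so the test says little about them. Of 25 tested members the calcium-binding protein gene SCGN rose (log2 change 1.88) and the transcription factor gene NKX2-2 fell by 0.72 (1 and 1 adjusted over the list alone; camera adjusted p = 0.344). NEUROD1 stood at 4.49 CPM at day 0 and 3.19 at day 6, SYP at 2.84 and 3.77, and the tuft cell factor gene POU2F3 at 196 and 160. EZH2 stood at 181 ± 17.9 and 169 ± 15.2 CPM, and the p53 target CDKN1A at 6.81 and 10.1. None of these was called with all libraries, and with the replicate block and without ΔNp63 day 1 replicate 3 POU2F3 (-0.30) and CDKN1A (0.58) were (edgeR adjusted p = 0.00742 and 0.00879). Single members rose in 3 lists that camera did not call. CD82 (1.01) rose among p53-family targets (camera adjusted p = 0.535; 2 rose and 2 fell adjusted over the list alone), and HES2 (1.29) in the Notch list (0.82; 1 adjusted over the list alone). COL3A1 rose among fibroblast markers (0.141; 2 rose and 1 fell adjusted over the list alone), from 2 counts at day 0 to 32 at day 6, a ratio of 21.8 (95% counting interval 5.55 to 188). Day 6 replicate 1 held 1.56 CPM of COL3A1 and the others 0.503 and 0.79, and without it the log2 change went from 4.18 to 3.56 (edgeR adjusted p = 0.113).

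In all, 318 genes changed in the ΔNp63 line at day 6, 253 up and 65 down, of which 188 and 34 changed at least 2-fold. The count was 784 without ΔNp63 day 1 replicate 3, 714 with the replicate block and 2221 with both, and each of these fits kept all 318. With both, 1284 genes rose and 937 fell. The count was 194, 175 and 196 without day 0 replicates 1, 2 and 3, and 186 and 207 without day 6 replicates 1 and 3. Of 34 named genes called there, 13 lost the call when 1 library was left out. AURKA, KLK7, SCGN, IFIT1, PRSS8, ITGA6, KCNN4 and NKX2-2 lost it without any 1 of the 6 libraries compared, with a highest edgeR adjusted p of 0.204, 0.17, 0.159, 0.215, 0.199, 0.177, 0.156 and 0.181. IFIT2 lost it without day 0 replicates 1 or 2 or day 6 replicates 2 or 3 (highest 0.107), and COL3A1 without day 0 replicates 2 or 3 or day 6 replicate 1 (0.113). MTHFD2 lost it without replicate 1 of either day (highest 0.0742), LAMB1 without day 0 replicate 3 (0.0585) and PPP1R1B without day 6 replicate 1 (0.0502). Without day 0 replicate 1 the log2 changes of SIPA1L2 and IL23R were 6.72 and 5.22. With only the libraries of the groups compared AURKA, IFIT2, MTHFD2 and NKX2-2 were not called (edgeR adjusted p = 0.13, 0.0611, 0.0629 and 0.0999), nor were AURKA, NKX2-2, IFIT1, PRSS8 and ITGA6 without a filter (0.132, 0.0893, 0.0713, 0.0662 and 0.0552).

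**Figure D2:**
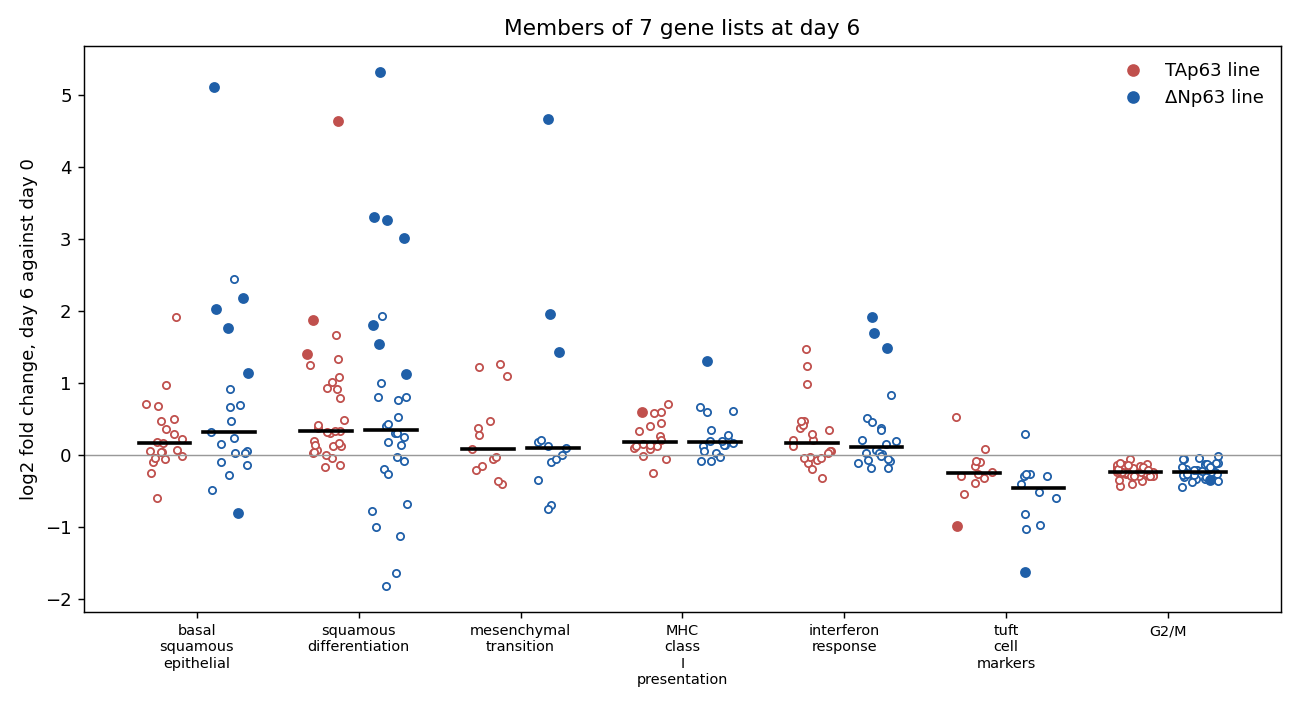
Log2 change from day 0 to day 6 of each tested member of 7 gene lists, red for the TAp63 line and blue for the ΔNp63 line, filled where the edgeR adjusted p is under 0.05, with a black bar at the list's median. In the ΔNp63 line KRT5 stands at 5.11 among basal squamous genes, and the highest squamous differentiation point is KLK7, whose day 0 count of 0 makes its fitted value depend on the prior count.

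By day 6 of TAp63 induction a smaller set of genes had risen. GPC4, a glypican (X chromosome, 133300103 to 133415489), rose from 0.138 ± 0.157 to 19.8 ± 1.80 CPM (log2 change 7.63 ± 0.586, edgeR adjusted p = 1.09e-07). SIPA1L2, a Rap GTPase activator (chromosome 1, 232397966 to 232515608), rose from 0.101 ± 0.0506 to 11.95 ± 2.44 CPM (6.95 ± 0.461, adjusted p = 2.14e-08 by edgeR). The magnesium channel gene TRPM6 rose from 0.135 ± 0.0255 to 5.22 ± 0.625 CPM and the collagen gene COL19A1 from 1.22 ± 0.257 to 19.1 ± 1.54. ATP1B2, a sodium pump subunit, went from 11.6 ± 1.18 to 110 ± 23.2 CPM, ZCCHC24 from 5.37 ± 0.412 to 41.7 ± 6.61 and IL23R from 0.291 ± 0.415 to 13.3 ± 2.96. The falls were those of BMX, from 73.0 ± 6.63 to 36.7 ± 5.24 CPM, and ART3, from 7.09 ± 0.459 to 2.08 ± 0.114.

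Among 30 squamous differentiation genes 3 rose under TAp63 at day 6 (7 adjusted over the list alone). They were SPRR3, a small proline-rich protein of the cornified envelope (6.53 ± 1.67 to 24.3 ± 6.69 CPM, log2 change 1.87), S100A14 (1.41) and KLK7. KLK7 had 3 counts at day 0 and 75 at day 6, a ratio of 28.2 (95% counting interval 9.29 to 140). Camera called the list higher (adjusted p = 1.56e-11; adjusted p = 0.0777 with an estimated correlation). KRT13 stood at a log2 change of 1.24 and KRT5 at 0.50 ± 0.442, from 0.495 ± 0.128 to 0.711 ± 0.0597 CPM, neither past the threshold. KRT13 passed with the replicate block and without ΔNp63 day 1 replicate 3 (log2 change 1.22, edgeR adjusted p = 6.76e-07), where 10 squamous differentiation genes rose. Of 21 basal squamous genes edgeR called 0 at day 6 (0 adjusted over the list alone; 4 at an unadjusted p under 0.05 and 0 by DESeq2), and camera gave an adjusted p of 0.0793. With the block and without that library 2 basal genes rose and 1 fell.

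B2M rose from 413 ± 12.2 to 628 ± 73.4 CPM in the TAp63 line, with the MHC class I list (1 adjusted over the list alone; camera adjusted p = 2.84e-05, adjusted p = 0.0403 with an estimated correlation). Interferon response genes lay higher as a list (camera adjusted p = 0.00605, adjusted p = 0.0403 with an estimated correlation). EdgeR called 0 of these 22 (1 adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 by DESeq2). Tuft cell markers lay lower, with BMX called (1 adjusted over the list alone; camera adjusted p = 5.15e-05, adjusted p = 0.143 with an estimated correlation). G2/M genes lay lower (camera adjusted p = 4.32e-10, adjusted p = 0.0403 with an estimated correlation), as did G1/S genes (5e-05; adjusted p = 0.272 with an estimated correlation). Simple epithelial genes lay higher (camera adjusted p = 0.0143, adjusted p = 0.67 with an estimated correlation) and cholesterol synthesis genes lower (0.0156; adjusted p = 0.325 with an estimated correlation). In these last 4 lists edgeR and DESeq2 each called 0 members, 0 passed when adjusted over the list alone, and 4, 1, 2 and 1 had an unadjusted p under 0.05. In the fit with the replicate block and without ΔNp63 day 1 replicate 3, edgeR called 6 G2/M genes lower, among them NDC80 (-0.38), BUB1 (-0.37), MKI67 (-0.37) and AURKA (-0.24), 2 G1/S genes lower (RRM1 and MCM3), 2 simple epithelial genes higher (KRT19 and SPINT2) and 0 cholesterol synthesis genes. It called 4 MHC class I and 2 interferon genes higher there and 4 tuft markers lower. Genes of these lists other than B2M and BMX were named after their values were seen. AGR2, a disulfide isomerase of secretory epithelia, rose (log2 change 1.32) among 6 columnar markers (1 adjusted over the list alone), a list camera did not call (adjusted p = 0.0559).

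The mesenchymal list in the TAp63 line at day 6 reached a camera adjusted p of 0.0528, 0.0461 with the replicate block and 0.0117 without ΔNp63 day 1 replicate 3. EdgeR called 0 of its 13 members (2 rose adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 by DESeq2), or 3 higher without that library with the block. ATF4 targets (camera adjusted p = 0.103), hypoxia genes (0.51) and the neuroendocrine list (0.287) were not called. NEUROD1 stood at 2.58 and 1.97 CPM, SYP at 4.27 and 3.28, POU2F3 at 218 and 182, EZH2 at 197 and 168, and CDKN1A at 6.11 and 8.74, all short of the threshold. POU2F3 fell by 0.26 on the log2 scale with the block and without ΔNp63 day 1 replicate 3 (edgeR adjusted p = 0.0485).

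In all, 69 genes changed in the TAp63 line at day 6, 67 up and 2 down, of which 53 and 1 changed at least 2-fold. The count was 154 without ΔNp63 day 1 replicate 3, 122 with the replicate block and 568 with both, all 69 kept in each. With both, 466 genes rose and 102 fell. The count was 45, 28 and 30 without day 0 replicates 1, 2 and 3, and 39 and 38 without day 6 replicates 2 and 3. The call of AGR2 was lost without any 1 of the 6 libraries compared (highest edgeR adjusted p = 0.321, without day 6 replicate 2). B2M and SPRR3 lost theirs without any of them but day 6 replicate 1 (highest 0.158 and 0.0902), and ART3 without day 6 replicate 2 (0.0511). The call of KLK7 was lost without day 0 replicate 2 (0.126), day 6 replicate 2 (0.0562) or day 0 replicate 3 (0.0552, where its log2 change went from 4.64 to 5.34). The log2 change of GPC4 was 8.37 and 6.84 without day 0 replicates 1 and 2, and that of IL23R 7.80 and 5.66. B2M was not called with only the libraries of the groups compared (edgeR adjusted p = 0.0847).

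Whether the lines responded differently was put to the interaction of line and day. Each isoform was carried by its own engineered line, so this test cannot part isoform from line or from TP63 level. At day 6 TP63 stood at 655 ± 41.3 CPM in the TAp63 line and 926 ± 100 in the ΔNp63 line. At day 6, 13 genes responded differently. KRT5, FXYD3, PADI3 and TGFBI rose more under ΔNp63, with differences, TAp63 minus ΔNp63, of -4.61 ± 0.590, -4.59 ± 0.452, -4.44 ± 0.530 and -3.44 ± 0.445 on the log2 scale (edgeR adjusted p = 0.00063, 2.83e-05, 0.000356 and 0.00063). In the TAp63 line FXYD3 stood at 2.42 ± 0.863 CPM at day 0 and 1.999 ± 0.680 at day 6, PADI3 at 3.56 ± 1.22 and 4.51 ± 0.828, and TGFBI at 1.73 ± 0.161 and 4.08 ± 0.529. LIMS2, a focal adhesion protein gene, and OLFML2A also rose more under ΔNp63 (-3.37 and -3.08). APOL4 (1.77), SLC1A7 (2.19) and TCF23 (3.27) went the other way. APOL4 fell from 40.5 to 15.4 ± 1.78 CPM under ΔNp63 and stood at 42.4 ± 2.99 and 55.1 ± 6.84 under TAp63, and TCF23 fell from 4.98 to 0.749 ± 0.355 CPM under ΔNp63. The remaining genes of the day 6 difference, chosen after their values were seen, were ANKS4B (3.03) and CACNA1H, ST6GALNAC2 and RCAN1 (-2.41, -2.05 and -0.75). GPC4 reached 2.88 ± 0.442 CPM under ΔNp63 and did not pass as a difference (3.04 ± 1.09, edgeR adjusted p = 0.999).

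As lists, basal squamous genes (camera adjusted p = 4.06e-05), mesenchymal genes (0.000865) and cholesterol synthesis genes (0.0161) lay lower in the TAp63 response, and ATF4 targets (2.51e-05) and tuft cell markers (0.00227) higher. None of these calls held: the adjusted p = 0.376, 0.204, 0.376, 0.204 and 0.334 with an estimated correlation. The members called were KRT5 and TGFBI (adjusted over the list alone, 5 basal and 2 mesenchymal members lower). EdgeR called 0 members of the other 3 lists, over all genes or adjusted over the list alone. DESeq2 called 0 of them too, and 4 ATF4, 1 cholesterol and 2 tuft members had an unadjusted p under 0.05. With the replicate block and without ΔNp63 day 1 replicate 3, edgeR called further members, named after their values were seen. Lower in the TAp63 response were 6 basal genes, KRT5 with TRIM29 (-1.85), S100A2 (-1.71), KRT15, FAT2 and PKP1, and 3 mesenchymal genes, TGFBI, LOX (-1.60) and FN1. Higher were 4 ATF4 targets, FGF21 (1.59), NUPR1 (1.28), TRIB3 and ATF5, the tuft marker PTGS1 (0.95) and the mesenchymal gene S100A4 (0.58). In that fit edgeR called 0 cholesterol synthesis genes (1 lower adjusted over the list alone). Immune markers were at 0.121, and at 0.023 upward without ΔNp63 day 1 replicate 3. The squamous differentiation list was not called (adjusted p = 0.757; median log2 difference -0.0697, mean 0.013; adjusted over the list alone 3 higher and 3 lower).

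The 13 genes of the day 6 difference were 44 without ΔNp63 day 1 replicate 3, 26 with the replicate block and 295 with both, all 13 kept in each. The count was 8 without TAp63 day 6 replicate 1, ΔNp63 day 0 replicate 1 or TAp63 day 0 replicate 2, and 7 without TAp63 day 6 replicate 2. It was 6 without ΔNp63 day 0 replicate 2, TAp63 day 0 replicate 3 or TAp63 day 6 replicate 3. SLC1A7 lost its call without any 1 of the 12 libraries compared but TAp63 day 0 replicate 1 (highest edgeR adjusted p = 0.151). OLFML2A lost it without any but that library and ΔNp63 day 0 replicate 3 (highest 0.24). LIMS2 lost it without ΔNp63 day 0 replicate 2, ΔNp63 day 6 replicate 1, TAp63 day 0 replicates 1 or 3 or any TAp63 day 6 library (highest 0.0954), and with only the libraries of the groups compared (0.0596).

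**Figure D3:**
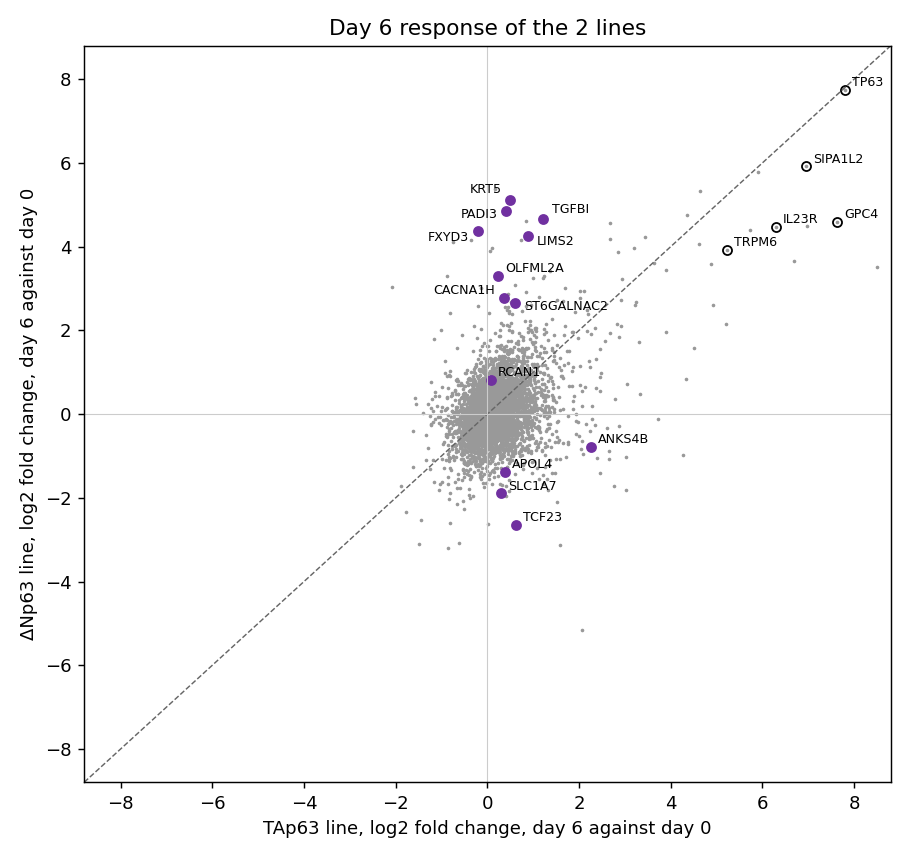
Log2 change from day 0 to day 6 in the TAp63 line (horizontal) against the ΔNp63 line (vertical) for all 15642 tested genes, with the 13 genes whose response differed in purple, TP63, SIPA1L2, GPC4, IL23R and TRPM6 as open circles, and the dashed line marking equal change. KRT5, FXYD3, PADI3 and TGFBI lie high on the ΔNp63 axis, and across genes Pearson's r is 0.436.

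Part of the day 6 response was common to both lines. SIPA1L2, GPC4, COL19A1, TRPM6, ATP1B2, ZCCHC24 and IL23R rose in each. Under ΔNp63 GPC4 rose by 4.59 on the log2 scale, COL19A1 by 3.45, TRPM6 by 3.92, ATP1B2 by 2.68 and ZCCHC24 by 3.24. Of 67 genes up under TAp63 and 253 up under ΔNp63, 42 were shared, where independent lists would share 1.08. BMX and ART3 made up the 2 genes down in both (0.00831 if independent), and edgeR called 0 genes in opposite directions, or 5 without ΔNp63 day 1 replicate 3 with the replicate block. Shared rises numbered 89 without that library, where independent lists would share 4.97. With the block as well they numbered 277, where independent lists would share 37.9. The lines share no library in this comparison, but both sets of calls rest on the same estimate of each gene's spread. A gene with a small spread is called more readily in both lines. The numbers for independent lists are therefore a reference only. Across all tested genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.436 and Spearman's rho = 0.370, and with r = 0.599 and rho = 0.482 over 11492 genes of at least 5 CPM.

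By day 3 of ΔNp63, KRT5 had risen to 7.54 ± 0.513 CPM (log2 change 3.53, edgeR adjusted p = 7.28e-06) and PADI3 to 93.6 ± 5.01 CPM (4.94). ALK, a receptor tyrosine kinase gene (chromosome 2, 29192774 to 29921586), rose from 0.265 ± 0.199 to 7.15 ± 1.05 CPM, and IL23R from 0.601 ± 0.494 to 29.8 ± 8.45. BMX (-1.52), ART3 (-2.43), KCNN4 (-1.48) and PPP1R1B (-1.55) fell. Among squamous differentiation genes 6 rose (7 adjusted over the list alone; camera adjusted p = 5.61e-05, adjusted p = 0.269 with an estimated correlation). Of these, chosen after their values were seen, SCEL reached a log2 change of 3.32, S100A8 3.35, KRT13 2.92 and EMP1 2.09. Among basal squamous genes 5 rose, KRT5 with NGFR (3.46), S100A2 (1.88), KRT15 (1.83) and TRIM29 (1.65), and ITGA6 fell by 0.87. Adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.000363, adjusted p = 0.344 with an estimated correlation). TGFBI rose by 3.502 in the mesenchymal list (2 adjusted over the list alone; camera adjusted p = 0.00263, adjusted p = 0.141 with an estimated correlation).

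Falls at day 3 of ΔNp63 were found among ATF4 targets, G2/M genes and tuft cell markers. Of 33 ATF4 targets 5 fell, among them MTHFD2 (-0.72), TRIB3 (-0.65) and PSAT1 (-0.61), and 13 adjusted over the list alone (camera adjusted p = 3.07e-13, adjusted p = 0.0403 with an estimated correlation). Of 35 G2/M genes AURKA (-0.54), TPX2 (-0.49) and CCNB1 (-0.48) fell, and 10 adjusted over the list alone (camera adjusted p = 5.25e-13, adjusted p = 0.0403 with an estimated correlation). BMX, AVIL (-1.22) and GFI1B (-0.67) fell among tuft cell markers (6 adjusted over the list alone; camera adjusted p = 4.43e-09, adjusted p = 0.0403 with an estimated correlation). G1/S genes (camera adjusted p = 5.71e-08; adjusted p = 0.147 with an estimated correlation) and hypoxia genes (0.0099; adjusted p = 0.427 with an estimated correlation) lay lower. EdgeR called 0 of either list, with 1 G1/S and 0 hypoxia genes adjusted over the list alone, 7 and 3 at an unadjusted p under 0.05, and 1 and 0 by DESeq2. Without ΔNp63 day 1 replicate 3 and with the replicate block it called 23 and 7 of them, all lower. Interferon response genes, with IFIT2 called (4 adjusted over the list alone), lay higher (camera adjusted p = 0.00852, adjusted p = 0.0403 with an estimated correlation). MHC class I genes, with B2M called (2 adjusted over the list alone), did too (0.014; adjusted p = 0.203 with an estimated correlation).

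In all, 344 genes changed in the ΔNp63 line at day 3, 260 up and 84 down. The count was 1000 without ΔNp63 day 1 replicate 3, 1078 with the replicate block and 3712 with both, each keeping all 344. With both, 1933 genes rose and 1779 fell. The count was 169, 144 and 217 without day 0 replicates 1, 2 and 3, and 229, 166 and 161 without day 3 replicates 1, 2 and 3. KCNN4 lost its call without any 1 of the 6 libraries compared but day 3 replicate 1 (highest edgeR adjusted p = 0.183), and PPP1R1B without any but day 0 replicate 1 (0.199). Without day 0 replicate 1 the log2 changes of ALK and IL23R were 5.47 and 6.44.

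At day 3 of TAp63, GPC4 (log2 change 6.25), SIPA1L2 (6.14) and IL23R (7.26) had risen, to 7.57 ± 0.921, 6.80 ± 1.5 and 26.02 ± 3.86 CPM, and BMX fell by 0.81 (edgeR adjusted p = 2.03e-06, 1.32e-07, 0.000218 and 0.00843). EMP1 (1.71) and KLK7 rose among squamous differentiation genes (5 adjusted over the list alone; camera adjusted p = 7.93e-08, adjusted p = 0.147 with an estimated correlation). MHC class I genes (camera adjusted p = 0.000308; adjusted p = 0.0791 with an estimated correlation) and interferon response genes (0.000294; adjusted p = 0.0403 with an estimated correlation) lay higher. ATF4 targets (camera adjusted p = 7.91e-10; adjusted p = 0.0403 with an estimated correlation) and G2/M genes (4.43e-09; adjusted p = 0.0453 with an estimated correlation) lay lower. Hypoxia genes (camera adjusted p = 0.00158; adjusted p = 0.311 with an estimated correlation), cholesterol synthesis genes (0.00655; adjusted p = 0.294 with an estimated correlation) and tuft cell markers (4.32e-05; adjusted p = 0.141 with an estimated correlation) were lower too. Simple epithelial genes were called higher (0.0446; adjusted p = 0.705 with an estimated correlation, and 0.0671 without ΔNp63 day 1 replicate 3). With the replicate block G1/S genes were called lower (0.0793, and 0.0461 blocked) and fibroblast markers higher (0.0561, and 0.03 blocked).

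Apart from the squamous genes and BMX, edgeR called 0 members of these lists at day 3 of TAp63. At an unadjusted p under 0.05 there were 2 MHC class I, 5 interferon, 6 ATF4, 3 G2/M, 3 hypoxia, 1 cholesterol and 2 simple epithelial genes. DESeq2 called 1, 1, 3, 1, 0, 0 and 0 of them. Without ΔNp63 day 1 replicate 3 and with the replicate block edgeR called 4 MHC class I and 3 interferon genes higher, 8 ATF4 and 8 G2/M genes lower, 1 hypoxia gene higher and 2 lower, and 2 simple epithelial genes higher and 1 lower. Adjusted over the list alone, 1 MHC class I, 4 interferon, 1 simple epithelial and 3 fibroblast genes rose, and 3 ATF4, 1 tuft and 1 fibroblast gene fell. In all, 68 genes changed, 67 of them up. The count was 151 without ΔNp63 day 1 replicate 3, 141 with the replicate block and 722 with both, all 68 kept in each. With both, 505 genes rose and 217 fell. The count was 32, 44 and 44 without day 0 replicate 2, day 0 replicate 3 and day 3 replicate 2. The call of BMX was lost without day 0 replicate 2 or day 3 replicate 3 (edgeR adjusted p = 0.112 and 0.0921). The log2 change of GPC4 was 6.99 and 5.45 without day 0 replicates 1 and 2, and that of IL23R 8.77 and 6.62.

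The day 3 responses differed between the lines for 7 genes, named after their values were seen. PADI3 (-4.08, TAp63 minus ΔNp63), KRT5 (-3.52), LIMS2 (-3.48), FXYD3 (-3.18), TGFBI (-3.02) and CCDC159 (-1.20) rose more under ΔNp63, and TCF23 differed by 2.62. The edgeR adjusted p lay between 0.0024 for PADI3 and 0.0407 for CCDC159. The count was 20 without ΔNp63 day 1 replicate 3 and 149 with that and the replicate block. It was 2 without TAp63 day 3 replicate 2 or TAp63 day 0 replicate 3. It was 3 without TAp63 day 0 replicate 1, TAp63 day 3 replicate 3, ΔNp63 day 0 replicate 2 or ΔNp63 day 3 replicates 1 or 2, and 4 without TAp63 day 3 replicate 1, TAp63 day 0 replicate 2 or ΔNp63 day 3 replicate 3. At day 1 edgeR found 0 genes whose response differed, with 530 at an unadjusted p under 0.05. DESeq2 called 1 there, with 713 unadjusted, and edgeR called 1 without ΔNp63 day 1 replicate 3 and 2 with that and the replicate block.

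After 1 day of TAp63 induction TP63, IL23R (0.291 ± 0.415 to 17.98 ± 16.7 CPM), RTN4RL2, a Nogo receptor homolog (5.63 ± 0.953 to 36.6 ± 26.9 CPM), and ATP1B2 (11.6 ± 1.18 to 67.9 ± 67.0 CPM) had risen. Their edgeR adjusted p were 0.00238, 0.00641 and 0.00641 after TP63, and the spread at day 1 was about as wide as the mean for IL23R and ATP1B2. Replicate 2 of day 1 stood highest, with 36.8 CPM of IL23R against 4.98 and 12.2 in replicates 1 and 3, 67.6 of RTN4RL2 against 21.3 and 20.9, and 145 of ATP1B2 against 24.1 and 34.5. Without it the log2 changes went from 6.76 to 5.63 for IL23R, from 2.71 to 1.90 for RTN4RL2 and from 2.55 to 1.32 for ATP1B2 (edgeR adjusted p = 0.0117, 0.0749 and 0.0117). With only the libraries of the groups compared these 3 genes were not called (edgeR adjusted p = 0.177, 0.27 and 0.971). NGFR, the low-affinity neurotrophin receptor of basal cells, rose by 3.87, the called basal squamous gene (1 adjusted over the list alone). Camera gave that list an adjusted p of 0.415 downward, with a median log2 change of -0.0959 and a mean of 0.0932. Hypoxia genes (camera adjusted p = 3.07e-13, adjusted p = 0.0403 with an estimated correlation) and tuft cell markers (8.5e-09, adjusted p = 0.0403 with an estimated correlation) lay lower. Cholesterol synthesis (camera adjusted p = 0.000759) and ATF4 genes (0.00482) lay lower too (adjusted p = 0.207 and 0.309 with an estimated correlation). Neuroendocrine genes were called lower (0.038) and interferon genes higher (0.0484), with adjusted p = 0.269 and 0.132 with an estimated correlation. Their values were 0.0609 and 0.0722 with the replicate block, and 0.0505 and 0.0649 without ΔNp63 day 1 replicate 3.

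EdgeR called 0 members of these 6 lists at day 1 of TAp63, and 1 tuft marker fell adjusted over the list alone. At an unadjusted p under 0.05 there were 4 hypoxia, 3 tuft, 0 cholesterol, 0 ATF4, 2 neuroendocrine and 1 interferon genes, and DESeq2 called 1 tuft marker and 0 others. Without ΔNp63 day 1 replicate 3 and with the replicate block edgeR called 3 tuft and 1 hypoxia gene lower. Simple epithelial genes were lower at 0.113, and at 0.03 without ΔNp63 day 1 replicate 3. Fibroblast markers were higher at 0.0861, and at 0.0383 with the block, with a median log2 change of 0.412, or 0.180 with COL3A1 at its bound. In all, 19 genes changed, all upward. The count was 27 without ΔNp63 day 1 replicate 3, and 140 with that and the replicate block, 85 up and 55 down. It was 4, 7 and 12 without day 0 replicate 2, day 0 replicate 3 and day 1 replicate 2. IL23R lost its call without day 0 replicate 2 (log2 change 6.11, edgeR adjusted p = 0.0668) or replicate 3 (0.052), and stood at 8.27 without day 0 replicate 1. RTN4RL2 lost its call without day 0 replicates 2 or 3 or day 1 replicate 2, and ATP1B2 without any 1 of the day 0 libraries (highest 0.088 each).

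After 1 day of ΔNp63 induction the risen genes included PADI3 (3.04 ± 0.0653 to 23.7 ± 17.1 CPM, log2 change 3.13, edgeR adjusted p = 0.000188), IL23R (0.601 ± 0.494 to 25.7 ± 25.6 CPM, 5.22) and the pseudogene FAM86B3P (2.07 ± 0.534 to 13.8 ± 13.9 CPM, 2.42). Replicate 3, the library that stood apart, held 55.2 CPM of IL23R where replicates 1 and 2 held 11 and 10.8, 29.9 of FAM86B3P where they held 5.93 and 5.62, and 3.99 of PADI3 where they held 34.2 and 33.0. Without it the log2 changes were 4.25, 1.49 and 3.46 (edgeR adjusted p = 0.00646, 0.00186 and 1.49e-09). BMX fell from 65.0 ± 4.67 to 34.8 ± 1.38 CPM. With only the libraries of the groups compared none of these 4 genes was called (edgeR adjusted p = 0.942 each). Tuft cell markers were lower (camera adjusted p = 1.32e-09, adjusted p = 0.0403 with an estimated correlation), as were hypoxia genes (3.09e-07; adjusted p = 0.143 with an estimated correlation) and cholesterol synthesis genes (4.09e-05; adjusted p = 0.132 with an estimated correlation). Neuroendocrine genes (camera adjusted p = 0.00117; adjusted p = 0.081 with an estimated correlation) and ATF4 targets (0.00482; adjusted p = 0.31 with an estimated correlation) were lower too. These 5 calls held without replicate 3 of the group. Adjusted over the list alone, 7 tuft, 7 hypoxia, 2 neuroendocrine and 1 ATF4 genes fell, and 1 of each rose. Beyond BMX, edgeR called 0 members of the 5 lists, while 8 tuft, 10 hypoxia, 5 cholesterol, 5 neuroendocrine and 11 ATF4 genes had an unadjusted p under 0.05, and DESeq2 called 4, 5, 0, 3 and 2.

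Replicate 3 of ΔNp63 day 1, with 835 CPM of VIM where the other libraries of the series held at most 21.6, decided further lists. With it, simple epithelial (camera adjusted p = 9.82e-08), HOX cluster (0.000185), basal squamous (0.0221) and squamous differentiation genes (0.0146) were called lower and mesenchymal genes (0.00997) higher. Their adjusted p = 0.282, 0.331, 0.613, 0.523 and 0.201 with an estimated correlation, and 0.0586, 0.829, 0.158, 0.923 and 0.0896 without the library. Medians and means differed in sign for HOX cluster (-0.213 and 0.0732), basal squamous (-0.18 and 0.0304) and squamous differentiation genes (-0.157 and 0.13). EdgeR called 0 members of the 5 lists. Adjusted over the list alone, 7 mesenchymal, 1 basal and 1 squamous differentiation genes rose and 1 basal gene fell. At an unadjusted p under 0.05 there were 4 simple epithelial, 4 HOX, 2 basal, 6 squamous differentiation and 7 mesenchymal genes, and DESeq2 called 0, 1, 1, 1 and 3. Interferon genes (0.505; 1 adjusted over the list alone) reached 0.0338 without the library.

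**Figure D4:**
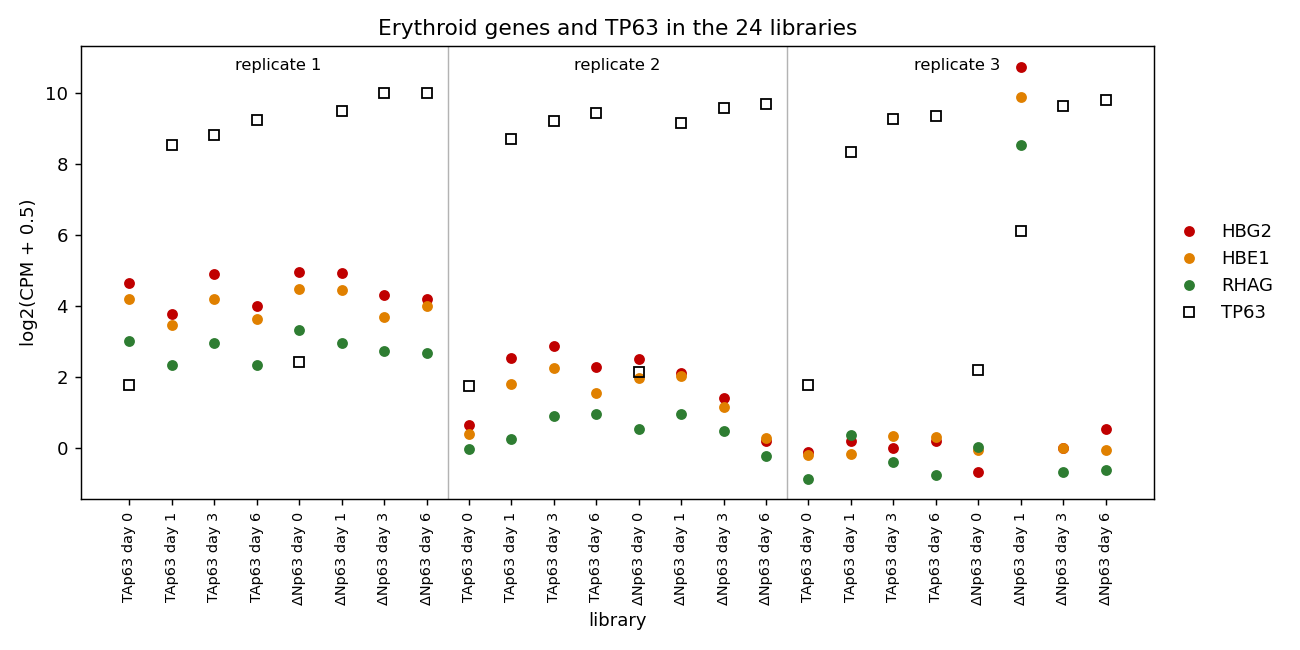
Levels of the globin genes HBG2 and HBE1, the erythroid membrane gene RHAG and TP63 as log2(CPM + 0.5) in each of the 24 libraries, arranged by replicate number. HBG2 stands at 1730 CPM in ΔNp63 day 1 replicate 3, at 13.4 to 30.6 CPM in the replicate 1 libraries and at most at 0.948 CPM in the other replicate 3 libraries.

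In all, 15 genes changed at ΔNp63 day 1, 14 up and 1 down, with 1901 at an unadjusted p under 0.05 and 500 called by DESeq2. The count was 29 without replicate 3 (all 15 kept) and 134 with that and the replicate block, 87 up and 47 down. It was 777 and 1101 without day 1 replicates 1 and 2, which leave replicate 3 as 1 of a pair, and 9, 4 and 3 without day 0 replicates 1, 2 and 3. The calls of BMX and FAM86B3P were lost without any 1 of the day 0 libraries (highest edgeR adjusted p = 0.112 and 0.338) and that of IL23R without day 0 replicates 2 or 3 (0.0958 and 0.0736), and the log2 change of IL23R was 5.96 without day 0 replicate 1.

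Between days 1 and 6 of TAp63 GPC4 (log2 change 4.40), SIPA1L2 (2.24), TRPM6 (2.25) and COL19A1 (1.95) rose. SPRR3 rose from 4.97 ± 0.967 to 24.3 ± 6.69 CPM. The edgeR adjusted p of these 5 genes were 3.63e-05, 0.00167, 0.00361, 0.00238 and 0.00361. In all, 47 genes changed, all upward. The count was 142 without ΔNp63 day 1 replicate 3, 112 with the replicate block and 652 with both, all 47 kept in each. With both, 509 genes rose and 143 fell. The count was 29, 25 and 13 without day 1 replicates 1, 2 and 3, and 16 and 24 without day 6 replicates 2 and 3. Without day 1 replicate 2 the log2 change of GPC4 was 5.13, and TRPM6 was not called with only the libraries of the groups compared (edgeR adjusted p = 0.0621).

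Over the same days of ΔNp63, KRT5 (log2 change 4.39), LIPF (3.99), FXYD3 (3.85), TGFBI (3.44), GSTA1, a glutathione transferase (3.44), and SLC6A5, a glycine transporter (3.07), rose, with edgeR adjusted p between 2.4e-06 for FXYD3 and 0.000339 for LIPF. None of these 6 calls held with only the libraries of the groups compared (edgeR adjusted p = 0.199, 0.197, 0.197, 0.322, 0.199 and 0.376). The 6 largest falls among called genes with at least 5 CPM in the higher group and no overlap between libraries were those of TEX19 (-4.49), GBGT1 (-4.48), TNFRSF1B (-3.97), OSMR (-3.94), PTPRVP (-3.85) and NFATC2, with 0 counts at day 6. All 6 lost their call without replicate 3 of day 1 (edgeR adjusted p = 0.401, 0.251, 0.513, 0.421, 0.241 and 0.206), and without any 1 of the day 6 libraries (0.0605 to 0.159). Replicate 3 of day 1 held 105.7 CPM of TEX19 where replicates 1 and 2 held 2.53 and 2.63. Without that library the log2 changes of TEX19, GBGT1, TNFRSF1B, OSMR and PTPRVP were -0.776, -1.03, -0.802, -1.52 and -1.38. Of 405 changed genes, 244 up and 161 down, 226 were among the 313 called without that library, 239 of them up and 74 down. DESeq2, with all libraries, called 455 genes up and 760 down. The count was 1398 and 1785 without day 1 replicates 1 and 2, and 145, 154 and 137 without day 6 replicates 1, 2 and 3. It was 1343 without day 1 replicate 3 with the replicate block. Without day 1 replicate 2 the log2 change of KRT5 was 5.47.

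Before induction the lines differed in 2 genes. PCDH19, a protocadherin gene, stood at 1.92 ± 0.390 CPM in the TAp63 line and 6.59 ± 0.289 in the ΔNp63 line, and POU3F2, a neural POU factor gene, at 1.46 ± 0.366 and 5.34 ± 0.443. The log2 differences were -1.74 and -1.83 (edgeR adjusted p = 0.0463 and 0.0307). Both calls were lost when any 1 of the 6 day 0 libraries was left out, highest without TAp63 day 0 replicate 3 (0.418 and 0.346). In each of those fits edgeR called 0 genes, where with all libraries 148 had an unadjusted p under 0.05 and DESeq2 called 8. With only the libraries of the groups compared both calls were lost (edgeR adjusted p = 0.0886 and 0.129), as was that of PCDH19 without a filter (0.0504). The count was 7 without ΔNp63 day 1 replicate 3, 6 with the replicate block and 27 with both. TP63 itself differed by -0.56 ± 0.527 before induction (edgeR adjusted p = 1).

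The other lists were not called by camera at day 6 in either line. The adjusted p under TAp63 and ΔNp63 were 0.545 and 0.535 for p53-family targets, 0.141 and 0.82 for Notch, 0.898 and 0.684 for desmosome and 0.273 and 0.252 for polycomb repressive complex genes. They were 0.792 and 0.645 for HOX cluster, 0.415 and 0.746 for immediate early and heat shock, and 0.51 and 0.684 for hypoxia genes. Among markers of other cell types they were 0.0559 and 0.76 for columnar, 0.807 and 0.141 for fibroblast, 0.834 and 0.103 for immune and 0.126 and 0.51 for endothelial markers. Cholesterol synthesis genes were at 0.74 under ΔNp63, and hemidesmosome genes at 0.443 under TAp63. In the TAp63 line median and mean differed in sign for desmosome genes (-0.0163 and 0.126) and immune markers (-0.0619 and 0.00929), with the test downward for both.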

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

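Of the tests reported here, those of the erythroid genes in 1 library (level, thinning, swap and induction) and those of the ATF4 and HOX lists were chosen only after the result was seen.

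The responses of the TAp63 and ΔNp63 lines differed by the interaction test for 7 genes at day 3 and 13 genes at day 6. Isoform cannot be parted here from engineered line or TP63 level. The day 6 differences, TAp63 minus ΔNp63 on the log2 scale, were -4.61 for KRT5, -4.59 for FXYD3, -4.44 for PADI3, -3.44 for TGFBI, -3.37 for LIMS2 and -3.08 for OLFML2A. They were 1.77 for APOL4, 2.19 for SLC1A7 and 3.27 for TCF23. By the list test the day 6 responses differed for basal squamous (camera adjusted p = 4.06e-05), mesenchymal (0.000865), ATF4 (2.51e-05), cholesterol synthesis (0.0161) and tuft cell genes (0.00227). None of these 5 calls held: the adjusted p = 0.376, 0.204, 0.204, 0.376 and 0.334 with an estimated correlation. In 60 splits of the libraries, drawn with a fixed seed and the real one included, 4 gave as many genes as the 7 of day 3 (highest other 11) and 6 as many as the 13 of day 6 (highest other 64). Each of the other splits that gave as many kept the later-day libraries of the lines apart, and so still held the lines' difference at that day, so these shares do not settle whether chance can be excluded. The 64 genes of one of them point to a structure of the samples, while the 55 and 54 splits that mixed these libraries gave 0 genes by edgeR each. KRT5 at day 6 stood at 26.3, 19.7 and 21.3 CPM in the ΔNp63 libraries and at 0.643, 0.750 and 0.741 in the TAp63 libraries. At day 1 all 60 splits gave at least the 0 genes of the real one (highest other 4).

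Library ΔNp63 day 1 replicate 3 stood apart from its group. A list of 20 erythroid genes, written before its test, had a median log2 ratio of 5.79 over the other 2 libraries of the group (interquartile bounds 5.52 and 6.21), with 19 of the 20 higher and TP63 at 69.2 CPM, which is what RNA or reads of an erythroid-like cell type in this library would give. Loss of reads alone would not give this level, since 0 of 100 draws of the other libraries thinned to 1530847 counts reached its 8636 erythroid counts (141 to 328). Thinning keeps the proportions of a library. It therefore cannot tell whether foreign RNA made up a larger share of this library because its yield was low. A swap with another of the 23 libraries is argued against by their highest erythroid level, 3.87% of this one, and 1 day of ΔNp63 by the median log2 ratio of -0.141 from day 0 to day 1 in replicates 1 and 2. Foreign RNA, a library of other cells or a wrong label from outside the series may each account for it, and these were not told apart; HBG2 (1730 CPM), HBE1 (953), HBG1 (733) and RHAG (372) were its most abundant list genes, ANK1 was expressed in all libraries, and no sort or gate is named in the labels.

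Same-numbered libraries deviated together from their group means, with a mean correlation of 0.474 without ΔNp63 day 1 replicate 3. A small share of the same erythroid-like RNA in some replicate numbers is argued against as the whole cause: without 2547 genes at least 2 times higher in that library the correlation was 0.426. Shared culture or preparation days stay open, since the labels give no batch, and no biological explanation was tested.

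The day 6 response common to both lines has no doxycycline control of the parental cells here. Doxycycline acting through the ATF4 stress response would raise that list in both lines, which was not seen at day 6. Its median log2 changes were -0.0607 under TAp63, where camera did not call it (adjusted p = 0.103), and -0.248 under ΔNp63. Camera called it lower under ΔNp63 (adjusted p = 9.82e-08, and adjusted p = 0.0807 with an estimated correlation). At day 3 the list was called lower in both lines (camera adjusted p = 7.91e-10 under TAp63 and 3.07e-13 under ΔNp63, with adjusted p = 0.0403 each with an estimated correlation). Every library with doxycycline also had p63 induced, so these values cannot show what doxycycline alone does to the list. Other effects of doxycycline were not examined. EZH2 inhibition by the EPZ-6438 named in a label cannot be told apart from p63 induction. Its labelled days equal the days of doxycycline in every group. EdgeR called 0 HOX cluster genes in either line (0 under TAp63 and 1 under ΔNp63 at an unadjusted p under 0.05, and 0 by DESeq2). That does not decide whether the inhibitor acted, and other EZH2 targets were not examined. Induction of p63 stays among the open explanations as the one the design names.

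For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 19 and 0, 68 and 0, and 69 and 0 for TAp63 days 1, 3 and 6, with 1 split of 10 as large, the real one. They were 344 and 0 and 318 and 0 for ΔNp63 days 3 and 6, 47 and 0 and 405 and 0 for day 6 against day 1 under TAp63 and ΔNp63, and 2 and 0 for the lines at day 0, again with 1 of 10. At ΔNp63 day 1 they were 15 and 355, with 2 of 10 as large. The split with 355 genes put replicate 3 of day 1 with both replicate 1 libraries, which points to a structure of the samples.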

How the results depend on the processing

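The fit without ΔNp63 day 1 replicate 3, alone and with the replicate block, was chosen only after the result was seen. With DESeq2 size factors all 147 tested values of named genes kept their side of the threshold and, where called, their direction, as they did with the block and with TP63 left out of the library sizes. With DESeq2 142 did and 3 gained a call, while GBGT1 and TEX19 at ΔNp63 day 6 against day 1 had no adjusted p. Without a filter 141 did and 6 lost it, and with only the compared libraries 111 did, 27 lost and 1 gained it, and the other 8, among them COL3A1, KLK7, NFATC2 and OSMR under ΔNp63, did not pass the count filter. Without ΔNp63 day 1 replicate 3, 140 did, 6 lost and 1 gained a call, and with that and the block 129, 5 and 13. Leaving out other libraries gave 773 kept, 171 lost and 5 gained. In these counts a change of sign was ignored where neither fit called the gene, and TP63 was counted apart. Depth limits genes of few counts, such as KLK7, COL3A1, IFIT1 and IFIT2, and the library of 1530847 counts. Except where construction shows it, the cause was not tested.

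Without 1 library at a time, counts ran from 4 to 27 for TAp63 day 1, 32 to 151 for day 3, 28 to 154 for day 6 and 13 to 142 for day 6 against day 1. For ΔNp63 they ran from 3 to 1101, 144 to 1000, 175 to 784 and 137 to 1785. The differences between lines ran from 0 to 1 at day 1, 2 to 20 at day 3 and 6 to 44 at day 6, and 0 to 7 between the lines at day 0. The highest came without ΔNp63 day 1 replicate 3, except 1101 and 1785, which came without replicate 2 of ΔNp63 day 1.

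DESeq2 called 30 genes for TAp63 day 1, 121 for day 3 and 99 for day 6 against day 1. It called 500, 597 and 503 for ΔNp63 days 1, 3 and 6 and 1215 for day 6 against day 1. For the differences at days 1, 3 and 6 it called 1, 16 and 35, and at day 0 it called 8. With only the compared libraries edgeR called 8 for TAp63 day 1, 24 for TAp63 day 6 against day 1, 546 and 494 for ΔNp63 days 3 and 6, and 3 and 25 for the differences at days 3 and 6. It called 0 there for ΔNp63 day 1, for ΔNp63 day 6 against day 1 and at day 0, where with all libraries 1901, 2806 and 148 genes had an unadjusted p under 0.05. TP63 at ΔNp63 day 1 was at a log2 change of 6.72 in that fit (edgeR adjusted p = 0.942). At day 0 DESeq2 size factors gave 4 genes and no filter 1.

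The replicate block gave 141 and 122 genes for TAp63 days 3 and 6, 112 for day 6 against day 1, 1078 and 714 for ΔNp63 days 3 and 6, 26 for the day 6 difference and 6 at day 0. Beyond the values given with the results, the block changed no other call of a named gene or list where the numbers pair the libraries. They do not for ΔNp63 day 1 (correlations of pairs -0.0581, 0.235 and -0.286) nor for ΔNp63 day 6 against day 1 (0.00571, 0.239 and -0.167), where the block gave 29 and 1017 genes and called the Notch list at day 1 (0.0845, and 0.0336 blocked). The block without ΔNp63 day 1 replicate 3 gave 140, 722 and 568 genes for TAp63 days 1, 3 and 6 and 652 for day 6 against day 1. For ΔNp63 it gave 134, 3712, 2221 and 1343, for the differences at days 1, 3 and 6 it gave 2, 149 and 295, and at day 0 it gave 27. This pair of changes lowered the common biological coefficient of variation from 0.216 to 0.074.

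Of 144 list tests against day 0 camera called 54, 16 with an estimated correlation, and fry called 31. Without ΔNp63 day 1 replicate 3 the direction at ΔNp63 day 1 turned for basal squamous (camera adjusted p = 0.158) and squamous differentiation genes (0.923). With the block as well it turned for basal squamous (0.338) and G1/S genes (0.000939). The correlation of the day 6 responses across genes was 0.599 over genes of at least 5 CPM.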

Other observations

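All tests in this part were chosen only after the result was seen. With the replicate block and without ΔNp63 day 1 replicate 3, the fit with the smallest spread, members of the squamous differentiation list went opposite ways under ΔNp63 at day 6, with 14 of 30 risen and 4 fallen (16 and 5 adjusted over the list alone). KRT13 (log2 change 3.29) and KRT4 (3.01), keratins of the suprabasal esophagus, rose, with edgeR adjusted p of 1.24e-16 and 6.61e-08. Genes of the cornified envelope were in both sets. PPL (0.76), CSTB (0.53), CNFN (0.33) and CRNN (1.79) rose, with edgeR adjusted p of 5.05e-07, 3.24e-05, 0.0474 and 2.38e-06. SPRR2A (-1.59), SPRR2F (-1.09), SPRR2D (-1.88) and SPRR1B (-0.94) fell, with edgeR adjusted p of 2.38e-07, 0.000377, 0.019 and 0.0253. With all libraries and no block these 4 were not called, with SPRR2A at -1.64 (edgeR adjusted p = 0.248) and SPRR2F at -1.12 (0.0644). The SPRR2 genes are near-identical copies, so their separate values are uncertain.

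Under TAp63 at day 6 the same fit had SPRR3 up by 1.90 and KRT13 up by 1.22 (edgeR adjusted p = 6.34e-11 and 6.76e-07). The day 6 responses, TAp63 minus ΔNp63, differed by 3.15 for SPRR2D, 1.603 for SPRR3, 1.596 for SPRR2F and 1.52 for SPRR2A (edgeR adjusted p = 0.0121, 1.33e-05, 0.000828 and 0.000358). They differed by -2.08 for KRT13 and -3.15 for KRT4 (edgeR adjusted p = 8.16e-08 and 0.00209).

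The erythroid list summed to 129 to 222 CPM in the 8 replicate 1 libraries, 76.8 to 119 in the 8 replicate 2 libraries and 61.4 to 147 in the other 7 replicate 3 libraries, against 5740 in ΔNp63 day 1 replicate 3. Outside that library much of each sum was ANK1, which was expressed in all libraries. At TAp63 day 0 ANK1 made up 89.7 of 182 CPM in replicate 1, 71 of 76.8 in replicate 2 and 71.8 of 74.2 in replicate 3. HBG2 stood at 13.4 to 30.6 CPM in replicate 1, 0.647 to 6.89 in replicate 2 and at most 0.948 in the other replicate 3 libraries. None of the 20 erythroid genes is in a list fixed for the comparisons.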
